A study of Mus musculus with 62 samples.

How the data were processed

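The series profiled regulatory T cells (Treg) and CD4+ conventional T cells (Tconv) by RNA sequencing. The mice carried the vTreg53 T cell receptor (TCR) transgene (Tg+) or did not (Tg-), and a further set of mice carried a PPARg reporter. Per the labels' protocols, 1000 double-sorted C57BL/6 cells per library were lysed, cDNA was primed with oligo(dT), fragmented with Nextera XT, and sequenced as pairs of 25 bp reads on a NextSeq500. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.5.4 and counted with featureCounts. The featureCounts version, the annotation, the strand setting, and the treatment of duplicates and multi-mapping reads are not given in the sources used here. The values deposited by the authors were raw read counts per gene symbol for 52997 symbols in 62 libraries, with 1 column per library, and all 62 columns were matched to the labels.

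The 62 libraries formed 21 groups of 2 to 4 libraries. The labels do not say whether replicates were separate animals, so every p-value measures the spread between these samples. Replicate numbers paired libraries in 1 of 19 comparisons, PPARg+ against PPARg- Treg of Tg+ mice, and that comparison was also fitted with replicate number as a block. The lowest and highest library totals were 0.449 and 5.86 M counts (M, mega). A count floor of 3 per library corresponded to 0.512 to 6.68 CPM, and floors cover counting error only because the reads carry no molecular identifiers. Over the 63 pairs of libraries within a group, the chi-square per degree of freedom of genes with at least 20 counts was 1.69 to 17, so no library was a resampled copy of another.

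Counts were analysed with edgeR 4.0.16 and limma 3.58.1 under R 4.3.3. Libraries were fitted in 4 families: 36 Treg libraries of the vTreg53 line (12031 genes tested), 12 libraries for Treg against Tconv (11328 genes), 6 libraries of transduced cells (11412 genes), and 14 libraries of reporter mice (12713 genes). Genes were kept by filterByExpr, libraries were scaled by TMM (factors 0.87 to 1.13), and robust quasi-likelihood F tests (glmQLFit and glmQLFTest) were run on group means. The common biological coefficients of variation were 0.19, 0.188, 0.124 and 0.24 in that order. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, 2-sided, with no fold limit. The 19 comparisons between a pair of groups and 4 interactions, the tests, the gene lists, the naming rule and the alternatives were chosen before the data were examined, apart from the additions named as such. Levels are TMM-normalised counts per M counts (CPM), given as mean ± SD over libraries, and fold changes are log2 values ± standard error. Sums over markers, values of single libraries, the plots of genes and the additional observations use CPM over total counts, without TMM. Where every library of a group had 0 counts, the fold is a lower bound against 3 counts per library. Adjusted p-values for single genes are edgeR values unless another tool is named.

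The 17 gene lists, written from general knowledge, were VAT Treg hallmark (24 genes), lipid handling (20), Treg core (20), resting lymphoid (18), effector Treg (20), trafficking receptors (22), TCR activation (15), proliferation (21), type I interferon response (16), dissociation stress (16), helper lineage (14), B cell markers (12), myeloid markers (13), adipose stroma markers (13), CD8 and NK markers (10), immature thymocyte markers (9) and red cell markers (6). Several of these lists share genes, such as Ccr2 and S1pr1. Each list was tested with limma camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Where a list passed both, its only p is the one with the estimated correlation, other lone p-values are at the preset correlation, and a direction not mentioned for a list had 0 genes. Of 285 list tests, 139 passed at the preset correlation and 64 passed with an estimated correlation, and those 64 passed both. For length, not all of them are printed, and this choice was made after results were seen. Adipose stroma and red cell markers had at most 2 tested members in any family and received no list test. A VAT signature was taken from Tg- Treg at 10 weeks, as the 866 genes higher and 498 lower in visceral adipose tissue (VAT) than in spleen by at least 1 on the log2 scale. It was tested in 10 other comparisons, adjusted over 20 tests. For Tg+ against Tg- splenic Treg at 10 weeks, whose Tg- libraries define that signature, the one made at 20 weeks was used (1301 higher and 1221 lower).

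Named genes followed a rule. It took Foxp3, Pparg, Il1rl1, Klrg1, Gata3 and Ccr2 in every comparison, up to 4 members of each described list with the smallest adjusted p, and the 8 rising and 8 falling genes with the largest fold among changed genes of at least 10 CPM in the higher group and no overlap between groups. Predicted genes and immunoglobulin and TCR segments were left out of the last part. Up to 2 Trav and 2 Trbv segments that rose were taken to check the genotype labels, and 6 genes with the smallest adjusted p were taken per interaction. A pair of genes that this rule picked is not reported here and was not replaced. Coordinates came from GENCODE vM21 on GRCm38, which held 49365 of the 52997 symbols.

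The code was tested on simulated data built from the fitted means and spreads, with 200 changed genes per simulation. For 3 libraries per group like the splenic Treg at 10 weeks, 53% of genes changed by 2-fold and 83% of those changed by 4-fold were recovered. Simulated Tconv, transduced and Tg- reporter comparisons recovered 57%, 62% and 49% of 2-fold changes and 90%, 90% and 84% of 4-fold changes. False calls were 11, 6, 4 and 16 in turn.

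The alternatives were RLE size factors, no filter on low counts, limma voom with sample quality weights, DESeq2 1.42.0 with its own size factors, the compared groups alone, a replicate block, and leaving out each library in turn. For the lists and the signature they were an estimated correlation, a signature from the other age (from 20-week Tg+ Treg for splenic genotype at 10 weeks), and a limit of 2 on the log2 scale. Added after the data were seen were reporter libraries 1 and 2 or 3 and 4 alone, a myeloid marker covariate, 20-week Treg in place of 10-week Treg beside Tconv, and counts without a set of co-varying genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No library was left out of the comparisons. Raw reads, splicing and full receptor sequences were not analysed here.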

Results

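The table held 62 libraries of mouse T cells. For the vTreg53 line there were 12 Treg groups of 3 libraries each: thymus and spleen at 2 weeks of age, and spleen and VAT at 10 and 20 weeks, each from Tg+ and Tg- mice. Tconv of Tg+ mice at 10 weeks came from spleen (n = 3) and VAT (n = 3). Transduced Tconv of Tg+ mice came as control-transduced splenic cells, Foxp3-transduced splenic cells and Foxp3-transduced VAT cells (n = 2 each). From PPARg reporter mice at 8 weeks, splenic Treg were sorted as PPARg+ or PPARg-, with 4 libraries of each from Tg+ mice and 3 of each from Tg- mice. Total counts were 0.449 to 1.95 M in the 24 Treg libraries of 2 and 10 weeks and 1.61 to 3.61 M in the 12 of 20 weeks. They were 1.49 to 5.22 M for Tconv, 1.87 to 5.86 M for transduced cells and 1.34 to 4.32 M for reporter mice. The libraries also differed in kind: Gm42418, a locus overlapping ribosomal RNA, took 4.71% to 13.2% of counts in the 2- and 10-week Treg libraries and 1.08% to 2.27% at 20 weeks. It took 1.61% to 2.11% in Tconv, 1.03% to 2.15% in transduced cells and 2.12% to 3.88% in reporter mice. One splenic library of 2-week Tg- mice stood apart, with 0.449 M counts, 13.2% Gm42418 and 11796 genes detected.

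The receptor segments separated the genotypes. Trbv2 (GRCm38 chromosome 6, 41047340 to 41047995) took 78.6% to 98.6% of all Trbv counts in the 38 Tg+ libraries and 1.53% to 10.4% in the 24 Tg- libraries. Trav14n-3 (chromosome 14, 53370077 to 53370575) took 10.7% to 92% of Trav counts in Tg+ and 0% to 5.95% in Tg- libraries. Its share in Tg+ Treg was 89.6% to 92% in thymus, 90.2% to 91.9% in 2-week spleen, 68.6% to 91.8% in VAT, and 25.5% to 41.5% in spleen at 10 and 20 weeks. In splenic Treg of Tg+ reporter mice it was 29.7% to 71.9%. In unmodified and control-transduced Tconv it was 10.7% to 20.4%, and in Foxp3-transduced cells 36.1% to 42% in spleen and 73.7% to 86% in VAT. Of 6 protein-coding genes followed in every comparison, Foxp3 (chromosome X, 7573644 to 7595245) specifies Treg. Pparg (chromosome 6, 115360951 to 115490399) encodes a nuclear receptor of adipocytes and VAT Treg. Il1rl1 (chromosome 1, 40429570 to 40465415) encodes the IL-33 receptor ST2, and Klrg1 (chromosome 6, 122270596 to 122282882) an inhibitory lectin-like receptor. Gata3 (chromosome 2, 9857078 to 9890034) encodes a T cell transcription factor and Ccr2 (chromosome 9, 124101950 to 124113557) a chemokine receptor.

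**Figure D1:**
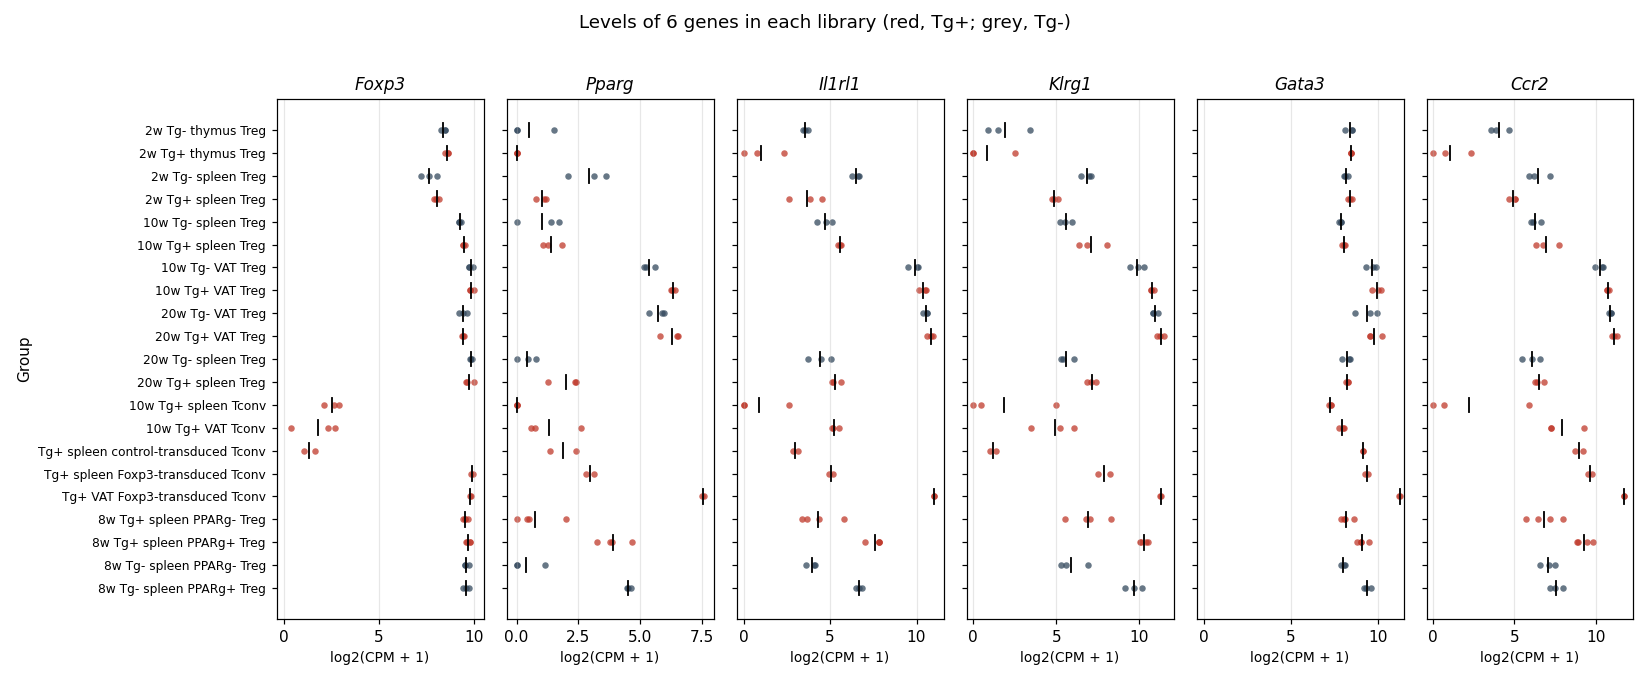
Level of 6 genes in every library, as log2(CPM + 1) with CPM over total counts, against group; points are libraries, black bars are group means, red is Tg+ and grey is Tg-. With TMM scaling Il1rl1 averaged 1060 to 1950 CPM in VAT Treg and 19.9 to 45.5 CPM in splenic Treg at 10 and 20 weeks, while Foxp3 stayed at 3.14 and 4.59 CPM in unmodified Tconv.

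Thymic Treg of 2-week mice were compared by genotype to ask what the transgenic receptor changed where Treg form (n = 3 per group). Gphn (123 ± 22 against 15.1 ± 6.46 CPM, log2 fold change 2.92 ± 0.29, adjusted p = 5.32e-10), which encodes gephyrin, was the strongest riser outside the receptor loci. With it rose Atp6v1d (1.27 ± 0.15, 281 against 116 CPM), a subunit of the vacuolar proton pump, Tlr1 (1.54 ± 0.19, 148 against 51.7 CPM), and Igfbp4 (1.48 ± 0.26, 319 against 113 CPM). Sgms1 (-1.38 ± 0.21, 30 ± 1.44 against 78 ± 3.76 CPM), a sphingomyelin synthase, fell. Foxp3 did not pass (378 ± 23.5 against 324 ± 29.9 CPM, adjusted p = 0.863), nor did Il1rl1 (1.55 ± 2.12 against 10.6 ± 1.25 CPM, adjusted p = 0.126). The receptor segments Trav14n-3 (422 against 1.44 CPM), Trbv2 (1840 against 16.6 CPM) and Trbv13-1 (390 against 6.72 CPM) rose. Among Treg core genes 0 of 20 passed (3 down adjusted over the list alone, adjusted p = 0.0338). Nrp1 was 160 ± 6.03 against 225 ± 12.1 CPM and Itgae 38 ± 4.25 against 93.9 ± 25.1 CPM. Among trafficking receptors 0 of 21 passed (5 down adjusted over the list alone, adjusted p = 0.0463). Among resting lymphoid genes 1 of 18 rose (1 up adjusted over the list alone, upward, adjusted p = 0.0342, or adjusted p = 0.249 with an estimated correlation), and the riser was Igfbp4. Of immature thymocyte markers 0 of 5 passed (downward, adjusted p = 0.0307, or adjusted p = 0.0921 with an estimated correlation). In all, 27 genes rose and 19 fell. Among these, Camk2n1, Sema4a, Dtx1, Lats2 and Nfkbid rose and C78197, Wls, Nkg7, Mctp1, Sntb1 and Tiam1 fell, and each lost its call when some single libraries were left out. The total of 46 was 24 without Tg+ replicate 2, 92 with voom weights, 171 with the 6 libraries alone and 188 with a replicate block.

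Splenic Treg of the genotypes were also compared at 2 weeks (n = 3 per group). The IL-33 receptor gene Il1rl1 (13.4 ± 8.44 against 92.5 ± 17.4 CPM, log2 fold change -2.85 ± 0.34, adjusted p = 1.17e-06) was lower in Tg+ mice. So were Fgl2 (-3.88 ± 0.68, 7.71 against 116 CPM), a fibrinogen-like secreted protein, and the chemokine Ccl5 (-3.66 ± 0.70, 2.39 against 33.1 CPM). The cytotoxic granule gene Nkg7 (-3.34 ± 0.49, 5.45 against 59.7 CPM), the transcription factor Maf (-1.92 ± 0.33, 35 against 128 CPM) and the chemokine receptor Cxcr6 (-2.66 ± 0.52, 7.89 against 53.3 CPM) fell too. Klrg1 (28.4 against 118 CPM, adjusted p = 0.00931) and Ccr2 (29 against 92 CPM, adjusted p = 0.0163) also fell. Pparg (1.05 against 7.6 CPM, adjusted p = 0.0812) and Foxp3 (257 ± 21.1 against 205 ± 48.5 CPM, adjusted p = 0.328) did not pass. Gphn (3.26 ± 0.33, 111 against 11.6 CPM) and the mitotic regulator Cdc20 (2.56 ± 0.46, 72.2 against 12.7 CPM) rose. Among proliferation genes 6 of 21 rose (20 up adjusted over the list alone, adjusted p = 0.00326), among them Mki67 (1.38 ± 0.30, 239 against 92.7 CPM), Top2a (1.88 ± 0.41, 453 against 123 CPM) and Mcm5 (1.12 ± 0.22, 186 against 87.4 CPM), with median 1.43. Of trafficking receptors 6 of 21 fell (8 down adjusted over the list alone, adjusted p = 0.00326), with Gpr183 (-1.35 ± 0.22) and Ccr3 (-2.50 ± 0.55) among the fallers. Of VAT Treg hallmark genes 6 of 23 fell (2 up and 7 down adjusted over the list alone, downward, adjusted p = 0.0014, or adjusted p = 0.127 with an estimated correlation), and of Treg core genes 3 of 20 fell, among them Nrp1 (-0.98 ± 0.14, 183 against 360 CPM) (adjusted p = 0.606). Markers of B cells summed to 386 to 489 CPM in Tg+ and 626 to 701 in Tg- libraries, and Ighm was 378 ± 60 against 638 ± 87.1 CPM (adjusted p = 0.0295). Of myeloid markers 0 of 5 passed (2 up adjusted over the list alone, upward, adjusted p = 0.0292, or adjusted p = 0.127 with an estimated correlation), and C1qb was 12.9 against 0 CPM (adjusted p = 0.0631). Altogether 112 genes rose and 103 fell. The library that stood apart, Tg- replicate 1, belongs here, and without it the total was 157. The total of 215 was 99 without Tg+ replicate 1, 87 without Tg+ replicate 2, 384 with voom weights and 348 with DESeq2. It was 43 with the 6 libraries alone and 31 with a replicate block, and with the 6 libraries alone the calls of Ccr2, Mki67, Mcm5, Gpr183, Ccr3 and Ighm were among those lost.

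Adult splenic Treg differed by genotype in few genes (n = 3 per group). Klrg1 was higher in Tg+ mice at 10 weeks (152 ± 96.2 against 49.3 ± 12.6 CPM, adjusted p = 0.0315) and at 20 weeks (127 ± 25.1 against 43.6 ± 14.4 CPM, adjusted p = 0.0271). Gphn rose at both ages (170 against 25.5 CPM at 10 weeks and 178 against 31.6 CPM at 20 weeks), as did Atp6v1d (0.78 ± 0.14, adjusted p = 0.00116) at 10 weeks and at 20 weeks (adjusted p = 8.75e-06). The chemokine receptor Ccr4 fell to 58.6 against 106 CPM at 10 weeks and 56.6 against 110 CPM at 20 weeks. At 20 weeks Myo6 (69.6 ± 13.5 against 9.55 ± 3.6 CPM, log2 fold change 2.87 ± 0.34, adjusted p = 7.95e-08), an unconventional myosin, rose. Aggf1 (-1.87 ± 0.29, 26.3 against 96.4 CPM), the aryl hydrocarbon receptor gene Ahr (-1.83 ± 0.45, 4.37 against 15.9 CPM) and the integrin gene Itgb1 (-1.10 ± 0.23, 131 against 280 CPM) fell. At 10 weeks Tnfsf11 (-2.50 ± 0.58, 6.33 against 33.3 CPM) fell. Foxp3 did not pass at 10 weeks (691 ± 45.2 against 627 ± 26.6 CPM) or 20 weeks (790 ± 134 against 828 ± 29.8 CPM). Il1rl1 was 45.5 ± 2.64 against 26.7 ± 8.02 CPM at 10 weeks and 35.4 ± 8.07 against 19.9 ± 9.28 CPM at 20 weeks, with adjusted p = 0.495 and 0.261. Pparg at 20 weeks was 2.97 ± 1.46 against 0.323 ± 0.322 CPM (adjusted p = 0.0529). The receptor segments Trav14n-3 (57.8 against 2.43 CPM) and Trbv2 (562 against 27.8 CPM) rose at 10 weeks, and Trav14n-3 (53.9 against 3 CPM) and Trbv2 (1120 against 29.5 CPM) rose at 20 weeks. Of the VAT Treg hallmark list, 1 of 23 rose (3 up adjusted over the list alone, upward, adjusted p = 0.000422, or adjusted p = 0.113 with an estimated correlation) at 10 weeks and 1 of 23 rose (4 up adjusted over the list alone, upward, adjusted p = 0.00637, or adjusted p = 0.66 with an estimated correlation) at 20 weeks. Among effector Treg genes 0 of 20 passed (6 up adjusted over the list alone, upward, adjusted p = 3.34e-05, or adjusted p = 0.113 with an estimated correlation) at 10 weeks, with granzyme gene Gzmb at 73.3 ± 58.7 against 15.1 ± 5.96 CPM. The counts were 19 higher and 68 lower at 10 weeks, and 22 higher and 36 lower at 20 weeks. Of these, 14 higher genes (0.0347 expected if independent, 10 of them TCR segments) and 19 lower genes (0.203 expected, 10 of them Trbv segments) were shared between the ages.

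These adult splenic counts were sensitive to single libraries. At 10 weeks the total of 87 became 28 or 33 without Tg- replicate 1 or 2, and 46, 32 or 26 without Tg+ replicate 1, 2 or 3. It became 136 with no filter, 136 with DESeq2, 183 with the 6 libraries alone, 164 with a replicate block and 46 without a set of 448 co-varying genes that is described with the additional observations. At 20 weeks the total of 58 became 106 without Tg+ replicate 1, 35 without Tg+ replicate 3, 127 with no filter, 121 with voom weights, 113 with the 6 libraries alone and 116 with a replicate block. The Klrg1 calls were lost without some single libraries of either genotype and with no filter at both ages, and those of Tnfsf11, Ahr, Ccr4 and Itgb1 without some single libraries.

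VAT Treg of Tg+ mice expressed less of the genes of resting lymphoid T cells than VAT Treg of Tg- mice at both ages (n = 3 per group). Tcf7 (11 ± 1.73 against 36.2 ± 7.68 CPM, log2 fold change -1.73 ± 0.29, adjusted p = 7.71e-05), which encodes the transcription factor TCF-1, was lower at 10 weeks and at 20 weeks (2.52 ± 2.75 against 21.2 ± 4.57 CPM, adjusted p = 1.87e-08). Nrp1, Lrrc32, Itgb1, Klf3, Gpr183 and Gpr15 also fell at both ages. The integrin gene Itgb1 was 70 against 292 CPM at 10 weeks and 37.4 against 125 CPM at 20 weeks. Of the resting lymphoid list, 11 of 18 fell (13 down adjusted over the list alone, adjusted p = 3.19e-05) at 10 weeks, with median -1.19. At 20 weeks 5 of 18 fell (1 up and 9 down adjusted over the list alone, adjusted p = 0.00914), with median -0.51.

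At 10 weeks the risers in VAT included Cxcr6 (817 ± 134 against 323 ± 156 CPM, log2 fold change 1.36 ± 0.28, adjusted p = 0.00628), a chemokine receptor. The prohormone convertase Pcsk1 (1.04 ± 0.25, 657 against 322 CPM), Ramp1 (1.10 ± 0.23), a receptor activity modifying protein, and Gphn (1.93 ± 0.25) rose with it. Among the fallers were Parp8 (-4.20 ± 0.47, 1.05 ± 0.575 against 19.6 ± 13 CPM), Gpr15 (-2.99 ± 0.43, 4.5 against 36.1 CPM), an orphan homing receptor, the ectonucleotidase Nt5e (-1.69 ± 0.22, 48.9 against 158 CPM), and Gbp2b (0 against 26.2 ± 24.6 CPM, at least 13-fold lower). The call of Cxcr6 was lost with the 6 libraries alone, those of Pcsk1 and Ramp1 also without Tg- replicate 1, and that of Gbp2b without some single libraries. Pparg was 88.8 ± 4.17 against 43.6 ± 8.06 CPM (adjusted p = 0.0722) and Il1rl1 1530 ± 188 against 1060 ± 242 CPM (adjusted p = 0.289). Klrg1 was 1970 ± 90.7 against 1060 ± 319 CPM (adjusted p = 0.186) and Foxp3 1050 ± 72.1 against 994 ± 95.5 CPM (adjusted p = 0.899). Among VAT Treg hallmark genes 2 of 23 rose (7 up adjusted over the list alone, adjusted p = 0.000599), with median 0.37. Of trafficking receptors 1 rose and 6 fell of 21 (3 up and 8 down adjusted over the list alone, adjusted p = 0.00622). Among Treg core genes 4 of 20 fell with median 0.06 and mean -0.32 (adjusted p = 0.134). Trav14n-3 (713 against 0.964 CPM) and Trbv2 (719 against 14.1 CPM) rose. Altogether 37 genes rose and 126 fell, and the total of 163 became 72 without Tg- replicate 1, 98 without Tg+ replicate 3 and 295 with voom weights.

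At 20 weeks the risers in VAT included Hilpda (791 ± 19.1 against 382 ± 45.8 CPM, log2 fold change 1.05 ± 0.17, adjusted p = 4.05e-05), a lipid droplet protein, and Hpgd (1.12 ± 0.21, 373 against 172 CPM), which degrades prostaglandins. Irs2 (1.38 ± 0.26, 137 against 52.5 CPM), an insulin receptor substrate, and the chemokine Cxcl2 (1.03 ± 0.21, 1330 ± 279 against 652 ± 177 CPM) rose too, and the Cxcl2 call was lost without some single libraries. Among the fallers were Trat1 (7.87 ± 3.32 against 63 ± 14.5 CPM, log2 fold change -2.96 ± 0.29, adjusted p = 1.96e-10), a TCR-associated adaptor, and P2rx7 (-2.94 ± 0.35, 4.65 ± 0.93 against 35.5 ± 2.95 CPM), the ATP-gated channel. Ikzf4 (-1.85 ± 0.16, 30 against 109 CPM), the Eos transcription factor of Treg, and Lrrc32 (-2.36 ± 0.34, 9.56 against 47.1 CPM), which encodes the TGF-beta docking receptor GARP, also fell. Foxp3 (750 ± 32.4 against 721 ± 92 CPM) and Pparg (84.7 ± 22.4 against 55.5 ± 11.9 CPM, adjusted p = 0.46) did not pass. Of VAT Treg hallmark genes 1 of 23 rose (2 up adjusted over the list alone, adjusted p = 0.00469). Among trafficking receptors 8 of 21 fell (1 up and 11 down adjusted over the list alone, adjusted p = 0.000746), among them Ccr6 (-1.82 ± 0.30). Of Treg core genes 1 rose and 5 fell of 20 (2 up and 6 down adjusted over the list alone, downward, adjusted p = 0.00034, or adjusted p = 0.0545 with an estimated correlation). Among proliferation genes 3 of 21 fell (10 down adjusted over the list alone, downward, adjusted p = 4.95e-08, or adjusted p = 0.0916 with an estimated correlation), with Stmn1 (-2.29 ± 0.45, 2.1 against 11 CPM). Among B cell markers 2 of 8 fell (5 down adjusted over the list alone, adjusted p = 0.025) in the same comparison, including Cd79b (-2.24 ± 0.40, 4.82 against 22.9 CPM). Their summed levels were 271 to 451 CPM in Tg+ and 569 to 691 in Tg- libraries. The myeloid marker Ctss (-1.54 ± 0.30, 30.5 against 88.5 CPM) fell as well. Trav14n-3 (331 against 1.01 CPM) and Trbv2 (865 against 21.6 CPM) rose, as did Gphn (2.52 ± 0.23). In all, 36 genes rose and 102 fell, and the total of 138 became 83 with the 6 libraries alone. Between 10 and 20 weeks, 16 higher genes (0.111 expected if independent, 11 of them TCR segments) and 57 lower genes (1.07 expected, 10 of them Trbv segments) were shared.

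**Figure D2:**
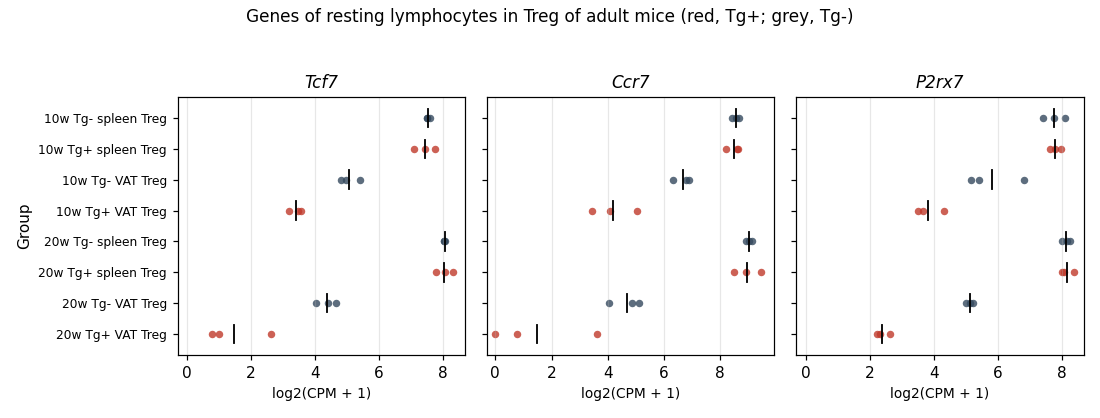
Levels of Tcf7, Ccr7 and P2rx7 in the 8 adult Treg groups as log2(CPM + 1), with CPM over total counts; points are libraries (n = 3 per group) and black bars are group means. With TMM scaling Tcf7 averaged 174 to 243 CPM in spleen, 21.2 and 36.2 CPM in Tg- VAT, and 2.52 and 11 CPM in Tg+ VAT.

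Whether the genotype effect differed between VAT and spleen was tested as an interaction. At 10 weeks 8 genes were more positive and 45 more negative in VAT. They included St6gal1 (-2.25 ± 0.28, adjusted p = 1.27e-06) and Ms4a4b (-1.55 ± 0.25, adjusted p = 0.000686). At 20 weeks the counts were again 8 and 45, with Tcf7 (-3.10 ± 0.40, adjusted p = 1.42e-06), Trat1 (-3.34 ± 0.37, adjusted p = 6.09e-08) and Ikzf4 (-1.64 ± 0.20, adjusted p = 4.67e-07). The 10-week total of 53 became 33 without Tg- spleen replicate 1, 19 without Tg- VAT replicate 1, 32 without Tg+ VAT replicate 1, 86 with no filter, 84 with the 12 libraries alone and 86 with a replicate block. The 20-week total of 53 became 33 without Tg- spleen replicate 1, 32 without Tg- VAT replicate 2, 102 with no filter and 22 with voom weights.

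Treg from VAT were compared with splenic Treg of the same genotype and age to describe the VAT program (n = 3 per group). In Tg- mice at 10 weeks, Il1rl1 was 1060 ± 242 CPM in VAT and 26.7 ± 8.02 CPM in spleen (log2 fold change 5.31 ± 0.27, adjusted p = 7.41e-17). The log2 fold change of Il1rl1 was 5.08 to 6.25 over the 4 genotype and age pairs. Pparg rose from 0.323 to 2.97 CPM in spleen to 43.6 to 88.8 CPM in VAT, and Klrg1 from 43.6 to 152 CPM to 1060 to 2720 CPM. Ccr2 rose to 1370 to 2460 CPM from 62.2 to 134 CPM, and Gata3 to 744 to 1120 CPM from 236 to 271 CPM. Foxp3 rose at 10 weeks in Tg- (994 ± 95.5 against 627 ± 26.6 CPM, adjusted p = 9.06e-05) and Tg+ mice (1050 ± 72.1 against 691 ± 45.2 CPM, adjusted p = 0.000204). It did not pass at 20 weeks (adjusted p = 0.224 and 0.682). Among the largest rises in Tg- mice at 10 weeks were Areg (7.85 ± 0.53, 593 against 2.45 CPM), which encodes the growth factor amphiregulin, and Anxa1 (8.77 ± 0.79, 393 against 0.819 CPM), the anti-inflammatory annexin. Ltb4r1 (7.66 ± 0.46, 293 against 1.39 CPM), the leukotriene B4 receptor, Pcsk1 (7.54 ± 0.49, 322 against 1.6 CPM) and Atf3 (88.4 ± 62.2 against 0 CPM, at least 36-fold higher) were others. At 20 weeks the chemokine receptor Ccr1 (10.36 ± 0.52, 425 against 0.215 CPM), the neutrophil-attracting chemokine Cxcl2 (10.51 ± 0.43, 652 against 0.437 CPM) and AA467197 (300 ± 101 against 0 CPM, at least 263-fold higher) rose in Tg- mice, and Cxcl2 (1330 ± 279 against 0 CPM, at least 1270-fold higher) in Tg+ mice. Among the largest falls were Dtx1 (-4.98 ± 0.38, 2.76 against 93.9 CPM) and Igfbp4 (-4.52 ± 0.46, 3.67 against 68.8 CPM) in Tg- mice at 10 weeks. In Tg+ mice Tgtp1 (0 against 23.2 ± 6.07 CPM, at least 16-fold lower), Cxcr5 (-7.90 ± 0.58, 0.562 against 169 CPM) and Ccr7 (-6.78 ± 0.49, 4.4 against 466 CPM) fell at 20 weeks.

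By list, VAT Treg hallmark genes rose in every pair. In Tg- mice at 10 weeks 22 of 23 rose (22 up adjusted over the list alone, adjusted p = 1.31e-06), and in each of the other pairs 21 of 23 rose. Resting lymphoid genes fell: 1 rose and 15 fell of 18 (1 up and 16 down adjusted over the list alone, adjusted p = 2.77e-05) in Tg- mice at 10 weeks, with median -1.61, or -1.38 with genes at 0 placed at their bound, and 1 rose and 16 fell of 18 in Tg+ mice at 20 weeks, with median -3.07, or -2.49 with genes at 0 placed at their bound. Tcf7 was 36.2 against 190 CPM and 2.52 against 243 CPM in these pairs. Of effector Treg genes 17 of 20 rose (17 up and 1 down adjusted over the list alone, adjusted p = 0.000485) in the first pair, with Cd44 (2.54 ± 0.20, 1260 against 216 CPM) and Prdm1 (2.83 ± 0.30). Among TCR activation genes 9 of 15 rose (9 up adjusted over the list alone, adjusted p = 0.000313), with Nr4a1 (4.43 ± 0.18, 1770 against 81.8 CPM) and Cd69 (2.97 ± 0.17, 1450 against 185 CPM). Beside them, of dissociation stress genes 11 of 16 rose (12 up adjusted over the list alone, adjusted p = 0.00495), with Fos (5.92 ± 0.35, 1380 against 22.6 CPM). They summed to 9970 to 23700 CPM in VAT and 2460 to 3210 in spleen over the 4 pairs. Of trafficking receptors 10 rose and 3 fell of 21 (adjusted p = 0.00151 with an estimated correlation) in Tg- mice and 10 rose and 5 fell of 21 (adjusted p = 0.0431 with an estimated correlation) in Tg+ mice at 10 weeks.

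Interferon response genes gave 3 of 15 fell (3 down adjusted over the list alone, downward, adjusted p = 0.000934, or adjusted p = 0.207 with an estimated correlation) in Tg- mice at 10 weeks. Of the same list 11 of 15 fell (13 down adjusted over the list alone, adjusted p = 0.0379) in Tg+ mice at 10 weeks. At 20 weeks 11 of 15 fell (downward, adjusted p = 9.35e-05, or adjusted p = 0.176 with an estimated correlation) in Tg- mice. In Tg+ mice 12 of 15 fell (downward, adjusted p = 3.74e-07, or adjusted p = 0.0721 with an estimated correlation). Usp18, an interferon target, was 15.1 against 86.7 CPM and 7.96 against 112 CPM at 10 weeks in Tg- and Tg+ mice. Among proliferation genes 14 of 21 rose (19 up adjusted over the list alone, upward, adjusted p = 2.46e-08, or adjusted p = 0.076 with an estimated correlation) in Tg- mice at 10 weeks, with Mki67 (1.86 ± 0.34, 93.6 against 26.5 CPM). In Tg+ mice at 10 weeks 16 of 21 rose (18 up adjusted over the list alone, upward, adjusted p = 2.29e-07, or adjusted p = 0.102 with an estimated correlation), and at 20 weeks 7 of 21 rose (adjusted p = 0.0553) in Tg- and 2 rose and 1 fell of 21 (adjusted p = 0.783) in Tg+ mice. Treg core genes were mixed. Of this list 9 rose and 6 fell of 20 (adjusted p = 0.215) and 10 rose and 7 fell of 20 (adjusted p = 0.66) at 10 weeks in Tg- and Tg+ mice, and 8 rose and 8 fell of 20 (adjusted p = 0.883) and 7 rose and 8 fell of 20 (adjusted p = 0.603) at 20 weeks. Ctla4 (2.27 ± 0.14, 1640 against 339 CPM) was among the risers and Izumo1r (-2.04 ± 0.18, 153 against 633 CPM), a folate receptor family member, among the fallers. Their medians were 0.62, 0.48, 0.16 and 0.05, their means -0.01, -0.27, -0.33 and -0.76, and the tests pointed up at 10 weeks and down at 20 weeks. Of lipid handling genes 4 rose and 2 fell of 13 (adjusted p = 0.0778) in Tg- mice at 10 weeks, with Dgat1 (3.23 ± 0.23) and Plin2 (3.56 ± 0.43) among them.

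Markers of other cells were counted beside these genes. Of B cell markers 2 rose and 1 fell of 8, 1 rose and 2 fell of 8, 3 rose and 3 fell of 8 and 1 rose and 4 fell of 8, with H2-Eb1 (3.67 ± 0.87, 11.4 against 0.836 CPM) among the risers, and summed to 958 to 1570 CPM in spleen and 567 to 1190 in VAT at 10 weeks. At 20 weeks the sums were 1710 to 2160 CPM in spleen and 271 to 691 in VAT. Of myeloid markers 1 of 5 fell, 1 of 5 fell, 2 of 5 fell and 2 of 5 fell, with median log2 fold changes of 1.4 (mean 0.65, test downward, adjusted p = 0.652), -0.68, -1.48 and -1.64. They summed to 296 to 489 CPM in spleen and 26.6 to 171 in VAT, with Ctss (-1.59 ± 0.27). Adipose stroma markers summed to 0 to 28.9 CPM in every group of the series. Among CD8 and NK markers 1 of 3 fell in Tg+ mice at 20 weeks and 0 of 3 elsewhere. Over all genes, 1331 rose and 827 fell in Tg- and 1808 and 1359 in Tg+ mice at 10 weeks, and 2287 and 2040 in Tg- and 2284 and 2086 in Tg+ mice at 20 weeks. Between genotypes, 1063 higher (200 expected if independent) and 562 lower genes (93.4 expected) were shared at 10 weeks, and 1727 (434) and 1414 (354) at 20 weeks. The 4 totals changed by less than 1.5 times under each alternative.

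VAT Treg at 20 weeks were compared with VAT Treg at 10 weeks to describe change with age (n = 3 per group). Hpgd rose in Tg- (172 ± 20.7 against 22.3 ± 8.09 CPM, log2 fold change 3.05 ± 0.27) and Tg+ mice (373 ± 53 against 40 ± 3.38 CPM, 3.22 ± 0.24). Cxcl2 rose in Tg- (652 ± 177 against 164 ± 66.9 CPM, adjusted p = 5.15e-07) and Tg+ mice (1330 ± 279 against 193 ± 14.7 CPM). The inhibitory receptor gene Pdcd1 rose as well (370 against 163 CPM and 557 against 237 CPM). S1pr1, the sphingosine phosphate receptor for egress from lymphoid tissue, fell in Tg- (131 against 298 CPM) and Tg+ mice (85.1 against 158 CPM). Foxp3 was lower at 20 weeks in Tg- (721 ± 92 against 994 ± 95.5 CPM, adjusted p = 0.0128) and Tg+ mice (750 ± 32.4 against 1050 ± 72.1 CPM, adjusted p = 0.00699). These calls were lost with no filter and without some single libraries, such as Tg+ replicate 3 of 10 weeks. In Tg+ mice Tbx21 (1.15 ± 0.442 against 23.8 ± 24 CPM, log2 fold change -4.28 ± 0.78, adjusted p = 0.000215), the lineage factor of Th1 cells, fell. Of proliferation genes 19 of 21 fell (20 down adjusted over the list alone, adjusted p = 0.0329) in Tg+ mice, with median -2.13. They included Stmn1 (-3.12 ± 0.44, 2.1 against 19.5 CPM) and Top2a (-3.15 ± 0.47, 14.8 against 131 CPM). In Tg- mice 2 of 21 fell (4 down adjusted over the list alone, downward, adjusted p = 0.000651, or adjusted p = 0.337 with an estimated correlation). Of the hallmark list 6 of 23 rose (8 up adjusted over the list alone, upward, adjusted p = 2.73e-06, or adjusted p = 0.0537 with an estimated correlation) in Tg- mice. In Tg+ mice 3 of 23 rose (3 up adjusted over the list alone, upward, adjusted p = 0.00183, or adjusted p = 0.141 with an estimated correlation). Of the resting lymphoid list 7 of 18 fell (2 up and 10 down adjusted over the list alone, downward, adjusted p = 0.000651, or adjusted p = 0.0973 with an estimated correlation) in Tg- mice and 2 rose and 4 fell of 18 (adjusted p = 0.618) in Tg+ mice. Of B cell markers 1 of 8 fell in Tg- mice and 2 of 8 fell (downward, adjusted p = 0.018, or adjusted p = 0.217 with an estimated correlation) in Tg+ mice. In all, 485 genes rose and 592 fell in Tg- mice, and 449 rose and 778 fell in Tg+ mice. Age coincided with the kind of library (share of Gm42418), so age and library preparation cannot be told apart. The Tg- total of 1077 became 522 without 10-week replicate 1 and 674 without 20-week replicate 3, and the Tg+ total of 1227 became 750, 796 and 720 without 10-week replicate 1, 10-week replicate 2 and 20-week replicate 3.

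Tconv from VAT and spleen of Tg+ mice at 10 weeks were compared to ask how far the tissue itself, without the Treg lineage, changes expression (n = 3 per group). The activation gene Nr4a1 (299 ± 83.7 against 18.7 ± 4.91 CPM, log2 fold change 3.97 ± 0.24, adjusted p = 1.75e-07), an early target of TCR signalling, rose in VAT. With it rose Ctla4 (4.02 ± 0.21, 48.8 against 3.17 CPM), the cytokine signalling inhibitor Cish (1.77 ± 0.16, 133 against 39.1 CPM) and Gata3 (0.72 ± 0.13, 236 against 143 CPM). Mmp9 (24 ± 11.4 against 0 CPM, at least 25.1-fold higher) and Nr4a2 (7.54 ± 0.59, 26.4 against 0.0608 CPM) were among the largest rises, and Slc16a5 (-2.26 ± 0.29, 45 against 212 CPM) and Id3 (-1.88 ± 0.23, 21.4 against 75.9 CPM) fell. Il1rl1 rose (36.5 ± 5.42 against 1.56 ± 2.7 CPM, adjusted p = 0.00269), a call lost with the 6 libraries alone. Pparg (2.05 ± 2.54 against 0 CPM, at least 2.14-fold higher) rose, with most of its counts in 1 library, and its call was lost without some single libraries. Foxp3 (3.14 against 4.59 CPM), Klrg1 (36.3 against 9.61 CPM, adjusted p = 0.332) and Ccr2 (304 ± 274 against 18.1 ± 30.9 CPM, adjusted p = 0.0906) did not pass. Among hallmark genes 9 of 22 rose (16 up adjusted over the list alone, adjusted p = 0.0203), with median 2.30, or 1.69 with genes at 0 placed at their bound. Of effector Treg genes 8 of 20 rose (15 up and 1 down adjusted over the list alone, adjusted p = 0.0432). Among TCR activation genes 5 of 15 rose (8 up adjusted over the list alone, adjusted p = 0.0203). Of proliferation genes 13 of 21 rose (19 up adjusted over the list alone, adjusted p = 0.0333). Among trafficking receptors 9 of 21 rose (12 up adjusted over the list alone, adjusted p = 0.0203). Of dissociation stress genes 11 of 16 rose (13 up adjusted over the list alone, adjusted p = 0.0203), with Junb (2.47 ± 0.12, 2480 against 449 CPM), and summed to 6730 to 8350 CPM in VAT and 2350 to 3020 in spleen. Among Treg core genes 7 rose and 1 fell of 19 (10 up and 1 down adjusted over the list alone, upward, adjusted p = 0.000136, or adjusted p = 0.104 with an estimated correlation). Of helper lineage genes 4 of 9 rose (7 up adjusted over the list alone, adjusted p = 0.0432). Among resting lymphoid genes 4 rose and 1 fell of 18 (downward, adjusted p = 0.00313, or adjusted p = 0.453 with an estimated correlation). Mitochondrial transcripts took 1.42% to 1.81% of counts in VAT and 0.512% to 1.11% in spleen. Altogether 675 genes rose and 156 fell, and 379 of the higher genes (76.5 expected if independent) and 72 of the lower (11.1 expected) were shared with Tg- Treg at 10 weeks. The total of 831 became 509 with the 6 libraries alone, and 506, 418 and 541 without spleen replicate 1, spleen replicate 2 and VAT replicate 3.

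Treg and Tconv of Tg+ mice were set side by side within each tissue (n = 3 per group). Foxp3 was 702 ± 44 against 4.59 ± 1.48 CPM in spleen (log2 fold change 7.16 ± 0.37) and 1050 ± 77.6 against 3.14 ± 2.59 CPM in VAT (8.46 ± 0.40). Ctla4 was 381 against 3.17 CPM in spleen and 1840 against 48.8 CPM in VAT, Lrrc32 (247 ± 56.7 against 0 CPM, at least 258-fold higher) rose in spleen, and Il10 (485 ± 133 against 0 CPM, at least 414-fold higher) rose in VAT. Il1rl1 was 46.2 against 1.56 CPM in spleen and 1530 against 36.5 CPM in VAT, and Pparg in VAT 88.7 ± 4.44 against 2.05 ± 2.54 CPM. Ccr2 was 1950 ± 72.8 against 304 ± 274 CPM in VAT and did not pass (adjusted p = 0.0828). Tcf7 was lower in splenic Treg (177 against 1190 CPM), and the survival gene Bcl2 (-5.44 ± 0.22, 11.1 against 485 CPM) and S1pr1 (-2.04 ± 0.12, 158 against 650 CPM) were lower in VAT. Of the core list 19 of 19 rose (19 up adjusted over the list alone, adjusted p = 0.00668) in spleen and 15 of 19 rose (16 up adjusted over the list alone, adjusted p = 0.0256) in VAT. Among hallmark genes 16 of 22 rose (17 up adjusted over the list alone, adjusted p = 0.0364) in spleen, with median 3.38, or 1.94 with genes at 0 placed at their bound, and 20 of 22 rose (21 up adjusted over the list alone, adjusted p = 0.00329) in VAT. Among resting lymphoid genes 1 rose and 10 fell of 18 (downward, adjusted p = 0.000164, or adjusted p = 0.286 with an estimated correlation) and 16 of 18 fell (downward, adjusted p = 7.83e-13, or adjusted p = 0.117 with an estimated correlation). Among B cell markers 4 of 6 rose (upward, adjusted p = 0.0229, or adjusted p = 0.156 with an estimated correlation) in spleen and 4 of 6 rose (upward, adjusted p = 0.0121, or adjusted p = 0.155 with an estimated correlation) in VAT, with Cd74 (4.10 ± 0.49, 44.1 against 2.32 CPM) in spleen. Among CD8 and NK markers 3 of 4 fell (downward, adjusted p = 0.0215, or adjusted p = 0.112 with an estimated correlation) in spleen and 3 of 4 fell (downward, adjusted p = 0.0359, or adjusted p = 0.136 with an estimated correlation) in VAT. In spleen 1987 genes rose and 1813 fell, and in VAT 2091 and 2089.

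The tissue difference itself was not the same in Treg and Tconv: 543 genes were more positive and 815 more negative in Treg by the interaction test. They included Gata3 (1.39 ± 0.18, adjusted p = 8.11e-06), Bcl2 (-5.52 ± 0.27, adjusted p = 1.31e-11), Gm2a (2.72 ± 0.16, adjusted p = 3.54e-11), a lysosomal lipid cofactor, and Dpp4 (-3.98 ± 0.26, adjusted p = 1.42e-10), a surface peptidase. Treg and Tconv libraries differed in kind (5.16% to 6.71% against 1.61% to 2.11% Gm42418). With 20-week Treg, whose share is closer to that of Tconv, in place of 10-week Treg, the totals were 1846 in spleen, 4868 in VAT and 1664 for the interaction. Of 3746, 4139 and 1345 calls among the 11216 genes tested both ways, 1413, 3064 and 687 were shared in the same direction.

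Foxp3-transduced splenic Tconv were compared with control-transduced ones (n = 2 per group). As the Trav14n-3 share rose too, Foxp3 alone was not tested. Foxp3 was 923 ± 57.4 against 1.51 ± 0.675 CPM (log2 fold change 9.21 ± 0.17, adjusted p = 2.28e-18). Klrg1 rose (231 ± 76.8 against 1.27 ± 0.39 CPM), as did Ccr3 (7.52 ± 0.27, 147 against 0.753 CPM) and Il1rl1 (2.19 ± 0.18, 31.3 against 6.83 CPM). Ctla4 (3.67 ± 0.11, 299 against 23.5 CPM), Gzmb (3.64 ± 0.15, 249 against 19.9 CPM), Maf (1.87 ± 0.10, 386 against 105 CPM) and Lrrc32 (33.1 ± 9.41 against 0 CPM, at least 21.8-fold higher) also rose, and Ccr2 (0.67 ± 0.14) rose less. Pparg (6.55 ± 1.24 against 2.8 ± 1.86 CPM, adjusted p = 0.11) and Gata3 (622 ± 42.8 against 534 ± 6.13 CPM, adjusted p = 0.0829) did not pass. Tcf7 (-1.26 ± 0.10, 231 against 554 CPM), the IL-7 receptor gene Il7r (-0.93 ± 0.08, 988 against 1880 CPM) and Ly6c2 (-3.77 ± 0.26, 8.38 against 115 CPM) fell. Among Treg core genes 16 of 19 rose (18 up adjusted over the list alone, adjusted p = 0.0242). Of effector Treg genes 15 rose and 2 fell of 20 (17 up and 2 down adjusted over the list alone, adjusted p = 0.0242). Among hallmark genes 14 of 23 rose (18 up adjusted over the list alone, adjusted p = 0.0394), with median 1.01, or 0.87 with genes at 0 placed at their bound. Of trafficking receptors 11 rose and 2 fell of 22 (12 up and 2 down adjusted over the list alone, adjusted p = 0.0394). Among proliferation genes 11 of 20 rose (12 up and 1 down adjusted over the list alone, adjusted p = 0.0394), with Mki67 (1.98 ± 0.26, 64.9 against 16.3 CPM). Of resting lymphoid genes 2 rose and 10 fell of 18 (3 up and 12 down adjusted over the list alone, adjusted p = 0.0394). Among B cell markers 3 of 3 rose (upward, adjusted p = 3.68e-05, or adjusted p = 0.0985 with an estimated correlation), with Ighm (1.25 ± 0.11, 924 against 389 CPM). They summed to 979 to 1000 CPM in Foxp3-transduced and 385 to 441 in control cells, where mitochondrial transcripts took 3.89% to 4.1% and 4.81% to 5.3% of counts. In all, 805 genes rose and 401 fell, and the total of 1206 became 691 without control replicate 1, where the lone control was assumed to vary like the other groups.

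Foxp3-transduced Tconv from VAT were compared with those from spleen (n = 2 per group). Mitochondrial transcripts took 1.28% of counts in both VAT libraries, which detected 30852 to 30935 genes, and 3.89% to 4.1% in spleen (23671 to 24350 genes). Pparg was 207 ± 13.3 against 6.55 ± 1.24 CPM (log2 fold change 4.97 ± 0.23) and Il1rl1 2290 ± 13.4 against 31.3 ± 4.17 CPM (6.19 ± 0.11). Klrg1 (2820 against 231 CPM), Gata3 (2680 against 622 CPM) and Ccr2 (3800 against 779 CPM) were higher in VAT too, while Foxp3 did not pass (994 ± 40.5 against 923 ± 57.4 CPM). The largest rises included Cxcl2 (12.57 ± 0.23, 1500 against 0.203 CPM), Areg (9.05 ± 0.18, 1330 against 2.44 CPM), Fos (9.28 ± 0.18, 4480 against 7.14 CPM) and Igfbp7 (27.7 ± 0.248 against 0 CPM, at least 22.6-fold higher). Tcf7 (-7.11 ± 0.19, 1.71 against 231 CPM), Satb1 (-6.05 ± 0.11, 10.6 against 711 CPM), Ccr7 (-7.02 ± 0.19, 2.27 against 314 CPM) and Iigp1 (-7.73 ± 0.34, 1.24 against 240 CPM), an interferon-inducible GTPase, fell. Of hallmark genes 21 of 23 rose (21 up and 1 down adjusted over the list alone, adjusted p = 0.0356). Among resting lymphoid genes 1 rose and 16 fell of 18 (1 up and 16 down adjusted over the list alone, adjusted p = 0.0356). Of effector Treg genes 16 rose and 2 fell of 20 (17 up and 2 down adjusted over the list alone, adjusted p = 0.0356). Among stress genes 15 of 16 rose (15 up adjusted over the list alone, adjusted p = 0.0422), summing to 23900 to 24000 CPM in VAT and 2220 to 2380 in spleen. Of interferon response genes 14 of 15 fell (14 down adjusted over the list alone, downward, adjusted p = 1.61e-09, or adjusted p = 0.0865 with an estimated correlation). Among B cell markers 3 of 3 fell (downward, adjusted p = 0.00355, or adjusted p = 0.165 with an estimated correlation). Of myeloid markers 2 of 4 fell (downward, adjusted p = 0.0188, or adjusted p = 0.165 with an estimated correlation). Over all genes 2396 rose and 2091 fell. Of these, 897 higher (271 expected if independent) and 479 lower genes (141 expected) were shared with the VAT and spleen comparison of Tg- Treg at 10 weeks.

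PPARg+ splenic Treg were compared with PPARg- splenic Treg of reporter mice at 8 weeks to ask which genes mark the splenic cells that express PPARg (n = 4 per group in Tg+, n = 3 in Tg-). The reporter sorted Pparg transcript, with 15 ± 6.44 against 0.923 ± 1.35 CPM in Tg+ mice (log2 fold change 3.68 ± 0.60, adjusted p = 0.000275). In Tg- mice Pparg was 21.6 ± 1.64 against 0.418 ± 0.724 CPM (5.32 ± 0.84, adjusted p = 0.000331). Il1rl1 rose in Tg+ (206 ± 50.7 against 23.7 ± 20.8 CPM) and Tg- mice (99 ± 9.74 against 15.1 ± 2.74 CPM). Klrg1 rose in Tg+ (1280 against 149 CPM) and Tg- mice (832 against 71.1 CPM), and Gata3 in Tg+ (557 against 290 CPM) and Tg- mice (646 against 267 CPM). Ccr2 rose in Tg+ (662 against 132 CPM, adjusted p = 0.00763) and did not pass in Tg- mice (186 against 142 CPM, adjusted p = 0.753). Its interaction did not pass either (adjusted p = 0.457). Foxp3 did not pass in Tg+ (852 against 754 CPM) or Tg- mice (763 against 811 CPM). The cytokine receptor Il9r (2.52 ± 0.28, 76.5 against 13.1 CPM), Ccr1 (4.20 ± 0.60, 27.1 against 1.25 CPM), and Rora (1.82 ± 0.22, 342 against 95.3 CPM) rose in Tg+ mice. Ccr8 (2.64 ± 0.32, 146 against 23.2 CPM), Tnfrsf9 (1.83 ± 0.20, 677 against 191 CPM) and Batf (1.33 ± 0.18, 291 against 117 CPM) rose in Tg- mice. In Tg+ mice Gata1 (-3.19 ± 0.29, 8.09 against 74.8 CPM), Ccr7 (-3.23 ± 0.39, 44.6 against 425 CPM) and Gpr83 (-3.17 ± 0.32, 43.3 against 397 CPM), an orphan receptor of Treg, fell. In Tg- mice the phosphatase gene Dusp2 (-2.73 ± 0.24, 39 against 262 CPM) fell.

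Hallmark genes gave 18 of 22 rose (20 up adjusted over the list alone, adjusted p = 0.0178) in Tg+ and 11 of 22 rose (12 up adjusted over the list alone, adjusted p = 0.0167) in Tg- mice. Among effector Treg genes 17 of 20 rose (18 up adjusted over the list alone, adjusted p = 0.0199) and 13 of 20 rose (16 up adjusted over the list alone, adjusted p = 0.0167). Of resting lymphoid genes 1 rose and 15 fell of 18 (1 up and 17 down adjusted over the list alone, adjusted p = 0.0199) and 1 rose and 15 fell of 18 (1 up and 16 down adjusted over the list alone, adjusted p = 0.0167). Among Treg core genes 10 rose and 6 fell of 20 (adjusted p = 0.0898) and 10 rose and 4 fell of 20 (upward, adjusted p = 0.00633, or adjusted p = 0.118 with an estimated correlation). Of trafficking receptors 12 rose and 5 fell of 22 (upward, adjusted p = 0.000262, or adjusted p = 0.113 with an estimated correlation) and 2 rose and 4 fell of 22 (adjusted p = 0.89). Among B cell markers 4 of 9 rose (upward, adjusted p = 0.00156, or adjusted p = 0.134 with an estimated correlation) and 1 of 9 rose (upward, adjusted p = 0.0111, or adjusted p = 0.215 with an estimated correlation), with Cd74 (2.18 ± 0.33, 189 against 40.4 CPM) in Tg+ mice. They summed to 1930 to 2470 CPM in PPARg+ and 1040 to 1400 in PPARg- libraries of Tg+ mice. In Tg- mice the sums were 2130 to 2940 and 1300 to 1490 CPM. Of myeloid markers 5 of 13 rose (12 up adjusted over the list alone, upward, adjusted p = 0.00187, or adjusted p = 0.42 with an estimated correlation) and 2 of 13 rose (9 up adjusted over the list alone, upward, adjusted p = 0.00793, or adjusted p = 0.499 with an estimated correlation). The complement gene C1qb was 51.1 ± 56.1 against 0.223 ± 0.314 CPM in Tg+ and 88.1 ± 101 against 0.139 ± 0.241 CPM in Tg- mice. Slc40a1, the iron exporter of macrophages, was 123 ± 143 against 1.35 ± 1.13 CPM and 138 ± 140 against 0.264 ± 0.458 CPM. These calls were lost without some single libraries. Red cell markers summed to 6.34 to 16.5 CPM in PPARg+ and 2.39 to 9.03 in PPARg- libraries of Tg+ mice, and to 10.5 to 254 (254 in replicate 3) and 0.744 to 6.02 in Tg- mice. Immature thymocyte markers summed to 47.2 to 81.4 and 109 to 146 CPM in Tg+ and to 51.9 to 93.8 and 105 to 130 in Tg- mice (1 of 5 fell, adjusted p = 0.257, and 1 of 5 fell, adjusted p = 0.162).

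Over all genes, 779 rose and 552 fell in Tg+ mice, and 481 rose and 567 fell in Tg- mice. Of these, 304 higher (29.5 expected if independent) and 251 lower genes (24.6 expected) were shared. The interaction of reporter and genotype held 50 more positive and 5 more negative genes, among them Rac1 (2.47 ± 0.27, adjusted p = 9.53e-05) and Dusp2 (2.41 ± 0.31, adjusted p = 0.000575). In Tg+ mice the count was 1720 with replicate number as a block, 99 with libraries 1 and 2 alone, among which the calls of Pparg, Il1rl1, Klrg1 and Gata3 were lost, and 1386 with libraries 3 and 4 alone. The Tg- total of 1048 became 583 and 562 without PPARg- replicates 1 and 2 and 679 and 516 without PPARg+ replicates 1 and 2. The interaction total of 55 became 36 without Tg+ PPARg- replicate 3, 20 and 14 without Tg- PPARg- replicates 1 and 2, and 84 without Tg- PPARg- replicate 3. It became 32, 13 and 83 without Tg- PPARg+ replicates 1, 2 and 3, 148 with no filter, 113 with DESeq2 and 18 without the co-varying genes.

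Genes of the VAT signature of Tg- Treg at 10 weeks moved as a set in Tg+ VAT Treg, with medians of 1.94 (701 of 866 rose) and -1.75 (363 of 498 fell), and these libraries share neither group with the signature. In Foxp3-transduced cells of VAT the medians were 1.61 (612 of 809 rose) and -1.29 (286 of 444 fell). PPARg+ splenic Treg had medians of 0.87 and -0.56 in Tg+ and 0.71 and -0.58 in Tg- mice, with 324 of 790 and 185 up genes risen and 174 of 492 and 158 down genes fallen. In VAT Tconv the up part had a median of 1.13 (305 of 815 rose), or 1.01 with genes at 0 placed at their bound, and the down part -0.26 (43 of 472 fell), or -0.122 without VAT replicate 3. Foxp3 transduction in spleen gave an up median of 0.56 (226 rose and 27 fell of 809) and a down median of -0.07 (49 rose and 47 fell of 444, mean 0.04). With an estimated correlation by limma camera, adjusted p was 1.1e-09 and 3.72e-09 for Tg+ VAT Treg, 0.00031 and 0.00556 for Foxp3-transduced VAT cells, 0.00174 and 0.00353 for PPARg+ Tg+, and 0.00211 and 0.00529 for PPARg+ Tg-. It was 0.00174 and 0.0665 for Tconv, and 0.00136 and 0.342 for Foxp3 transduction. Genotype moved it little: medians in Tg+ against Tg- spleen were 0.11 and -0.15 at 10 weeks with the 20-week signature (adjusted p = 0.122 and 0.00131 with an estimated correlation). They were 0.03 and -0.03 at 20 weeks, 0.02 and -0.11 at 2 weeks, and -0.11 and 0.02 in thymus. In thymus the down part had a mean of -0.04, and at 2 weeks in spleen the up part had a mean of -0.02, each opposite in sign to its median. Without Tg+ replicate 3 the 10-week up median in spleen was 0.055. At 20 weeks in spleen the down part was -0.002, -0.076 and -0.065 without Tg- replicate 1, Tg- replicate 3 and Tg+ replicate 3. It passed at the preset correlation (adjusted p = 0.00659) and not with an estimated correlation (adjusted p = 0.122).

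**Figure D3:**
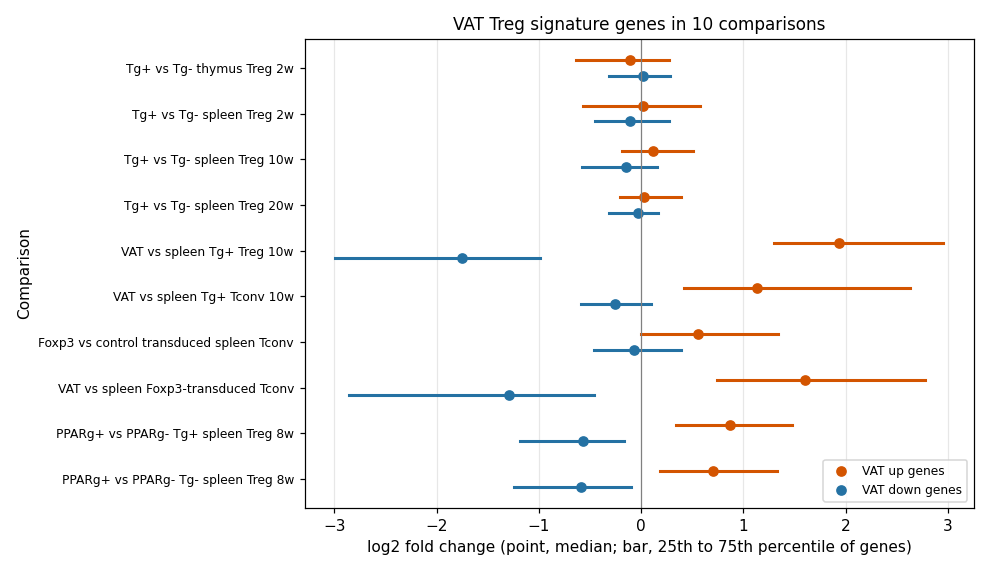
Log2 fold changes of the VAT signature genes in 10 comparisons; points are medians of the up and down genes and bars run from the 25th to the 75th percentile of genes. The up and down medians part in VAT and PPARg+ cells (1.94 and -1.75 in Tg+ VAT Treg, 0.71 and -0.58 in PPARg+ Tg- Treg).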

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

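The tests of a shared level, of the macrophage transcripts between libraries, of Pparg against them, with a myeloid covariate, of neighbouring risers and of splits by replicate number were chosen only after those results were seen. The other tests below were written beforehand. The interaction tests called 53 genes for tissue by genotype at 10 weeks, 53 at 20 weeks, 1358 for tissue by cell type and 55 for reporter by genotype. At 10 weeks the genotype effect in VAT minus that in spleen was -2.25 for St6gal1, -4.27 for Parp8, -1.55 for Ms4a4b, -2.26 for Patj and -2.60 for AC140209.1 on the log2 scale. At 20 weeks it was -3.34 for Trat1, -2.39 for Ms4a4b, -2.70 for Cd96, -4.23 for Clec2i, -1.64 for Ikzf4 and -3.10 for Tcf7. The tissue effect in Treg minus that in Tconv was 1.39 for Gata3, -5.52 for Bcl2, 2.72 for Gm2a, -3.35 for St6gal1, -3.98 for Dpp4, -3.62 for Cd96 and -3.96 for Clec2i. The reporter effect in Tg+ minus that in Tg- was 2.47 for Rac1, 2.63 for Mgat2, 2.41 for Dusp2, 1.80 for Anp32b, 1.99 for Pacsin2 and 1.81 for Snx20. Of 100 random splits fitted on the compared groups alone, 4 gave as many genes as the real 84 at 10 weeks (highest other 96) and 2 as many as the real 1358 for cell type (1880). For the reporter, 35 splits moved both libraries of a replicate number together, and only 1, the real one, gave 55 genes (highest other 10). At 20 weeks 5 gave as many as the real 42 (55). The tissue splits with most genes exchanged all libraries of one tissue and 1 of the other. The random splits and those of the reporter also broke up the genotype or cell type effect, so they cannot exclude chance.

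Of 52 values tested in the 2 groups of 4 libraries, 6 had a library far from the others. The 2.6 expected by chance does not hold where the others are 0. In PPARg- Treg of Tg+ mice, replicate 2 had 3.01 CPM of Pparg (others 0 to 0.414), 0.463 of Slc11a1, 0.926 of C1qa and 1.16 of Trf (others 0), and 211 of Trav14n-3 (others 55.4 to 73.5). In PPARg+ Treg of Tg+ mice, replicate 4 had 129 CPM of Il1rl1 (others 223 to 229).

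For 3 against 3 libraries, only 10 splits exist, too few for a share under 0.05, and only 1 of them, the real one, gave as many genes. Fits of the compared libraries alone gave for genotype 171 genes in thymus and 43 in spleen at 2 weeks, 183 in spleen and 160 in VAT at 10 weeks, and 113 in spleen and 83 in VAT at 20 weeks, with highest other splits of 2, 0, 0, 0, 0 and 21. VAT against spleen gave 2266 and 3255 genes at 10 weeks and 4037 and 3793 at 20 weeks in Tg- and Tg+ Treg, age gave 959 and 1086, Tconv gave 509, and Treg against Tconv gave 3643 in spleen and 3874 in VAT, each with a highest other of 0. PPARg+ against PPARg- in Tg- mice gave 1127 with a highest other of 1. In Tg+ mice 8 splits part all 4 presumed pairs by number, too few for a share under 0.05. Only 1 of them, the real one, gave 1207 genes, and the highest other was 1. Splits that keep some pairs together reached at most 38.

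A set of 448 genes varied within groups together with the mean of the 6 genes of the reporter interaction over the 36 Treg libraries (r over 0.5). The set held 443 genes outside those 6, which are left out of the counts below. Of the genes lower in Tg+ splenic Treg, 41 of 68 at 10 weeks (2.51 expected), 12 of 36 at 20 weeks (1.33) and 14 of 103 at 2 weeks (3.79) belonged to this set. So did 142 of 561 lower genes in PPARg+ Treg of Tg- mice (19.4) and 47 of 552 of Tg+ mice (19.1), whose libraries gave the 6 genes, and 107 of 801 genes higher with Foxp3 transduction (30.3). As members vary together, no p-value is given. The slope on GC content over all genes gave 2.4% and that on transcript length 0.6% of the members' median fold change at 10 weeks, which argues against both. A shared level that also varies between libraries of one group stays open. Within 2-week Tg- spleen the set's mean log2 level was 6.65 in replicate 1, which stood apart, and 5.65 and 5.32 in the others. With the set redefined without that library, 35 of 68 (1.57 expected) and 12 of 36 belonged to it. Without the 12 spleen libraries of 10 and 20 weeks 39 (4.95 expected) and 15 (2.62) did. At 10 weeks the level was 5.78 to 6.02 in Tg- and 5.25 to 5.62 in Tg+ spleen, without overlap, as 10% of splits give by chance, and at 20 weeks 6.17 to 6.29 and 5.66 to 6.2, with overlap. The genotype itself stays open as an untested explanation, and so do steps of sorting or library preparation.

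Of 13 myeloid markers 5 rose in PPARg+ Treg of Tg+ and 2 of Tg- mice, with list calls lost at an estimated correlation. In 3 of 7 PPARg+ libraries their sum was not above the 368 to 467 CPM of PPARg- libraries. Those 3 had 5.09 to 10.2 CPM of C1qb, against 0 to 0.674 in PPARg-. Between PPARg+ libraries the myeloid markers rose and fell together (median pairwise r = 0.89 over 66 pairs of 12 genes in 7 libraries, after removal of group means), which is consistent with RNA of macrophages in the sorted fraction. Macrophages as the only source of Pparg were argued against. Between these libraries log2 Pparg rose by 0.13 (95% confidence interval -0.11 to 0.38) per unit of the mean log2 level of 6 myeloid markers under 1 CPM in PPARg- Treg, where an only source gives 1, and in Tg- mice Pparg was 20.9 to 23.8 CPM while C1qb ran from 10.2 to 203. As the source of the VAT signature rise they were argued against too, because 98.8% of the median in Tg+ and 99.4% in Tg- mice was kept with a myeloid covariate. A myeloid program within PPARg+ Treg was not tested.

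Gphn (chromosome 12, 78226379 to 78684772) and Atp6v1d (chromosome 12, 78840725 to 78861638) rose in 6 of 6 genotype comparisons and lie 155953 bp apart. Outside the receptor loci these 2 were the only genes that rose in at least 4 of 6, so the test of an effect of the transgene on its neighbours (2 genes within 1 Mb of another) restates what prompted it, and this effect stays open. An effect reaching all genes around the site was argued against, since 8.33% of the 12 other tested genes within 1 Mb rose. A passenger variant near the transgene stays open too, and the insertion site is not given in the sources used here.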

How the results depend on the processing

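Only the estimates with libraries 1 and 2 or 3 and 4 alone, the myeloid covariate, 20-week Treg beside Tconv, and the counts without co-varying genes were chosen after the results were seen. Of 1435 values of named genes, 928 were past the threshold and 936 kept their direction and their side of it in every setting. At 5 the direction turned: in splenic Treg against Tconv with 20-week Treg, Ifih1 was -0.117, in VAT Ccnb1 was -0.26, Bub1 -0.057 and Bcl6 0.254, and Il1rl1 in the cell type interaction ranged from -4.338 (without spleen Tconv replicate 3) to 1.098. The cause was not tested for these or for the moves below, apart from the loss of calls with fewer libraries, which follows from fewer samples. With no filter, counts were 136 and 127 for genotype in spleen at 10 and 20 weeks, 86 and 102 for tissue by genotype, and 148 for reporter by genotype. With voom weights they were 92 in thymus, 384 in 2-week spleen, 295 in 10-week VAT, 121 in 20-week spleen and 22 for tissue by genotype at 20 weeks. DESeq2 gave 348 in 2-week spleen, 136 in 10-week spleen and 113 for the reporter interaction. The compared groups alone gave 171 in thymus, 43, 183 and 113 in spleen at 2, 10 and 20 weeks, 83 in 20-week VAT, 84 for tissue by genotype at 10 weeks and 509 in Tconv. A replicate block gave 188 in thymus, 31, 164 and 116 in spleen, and 86 for that interaction. With 20-week Treg, spleen Treg against Tconv gave 1846. PPARg+ in Tg+ mice gave 99 with libraries 1 and 2 alone. Without co-varying genes, 10-week spleen gave 46 and the reporter interaction 18. With an estimated correlation 64 list tests passed instead of 139. Leaving out single libraries gave ranges of 24 to 39 (thymus), 87 to 288 (2-week spleen), 26 to 76 (10-week spleen), 72 to 206 (10-week VAT), 35 to 106 (20-week spleen), 99 to 142 (20-week VAT), 19 to 53 and 32 to 56 (tissue by genotype at 10 and 20 weeks), 522 to 978 and 720 to 1338 (age in Tg- and Tg+), 418 to 883 (Tconv), 691 to 910 (Foxp3), 516 to 1005 (PPARg+ in Tg-), 939 to 1567 (in Tg+) and 13 to 84 (its interaction). For VAT against spleen they were 1486 to 1794 and 2480 to 2784 at 10 weeks, 3756 to 3925 and 3779 to 4071 at 20 weeks, and 3498 to 3647 in transduced cells, for Treg against Tconv 2897 to 3823 and 3548 to 4131, and for tissue by cell type 1033 to 1574.

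On the same side of the threshold (up and down), the 20-week signature gave 1.356 and -0.903 in Tg+ VAT Treg, 0.739 and -0.151 in Tconv, 1.392 and -0.715 in transduced VAT cells, 0.456 and -0.241 in PPARg+ Tg+, 0.481 and -0.381 in PPARg+ Tg-, and 0.27 with Foxp3 (up). A limit of 2 gave 2.872 and -3.25, 2.111 and -0.439, 2.557 and -2.878, 1.316 and -1.229, and 1.07 and -0.906 in the first 5, 0.868 with Foxp3 (up) and 0.176 and -0.138 in 10-week spleen, where the signature of 20-week Tg+ Treg gave 0.095 and -0.065. The 20-week signature also gave 0.063 (thymus, down), -0.041 and 0.017 (2-week spleen), 0.216 and -0.151 (20-week spleen, both partly built in, since it shares the Tg- libraries) and 0.126 (Foxp3, down). A limit of 2 also gave -0.146 and -0.144 (thymus), -0.012 and -0.179 (2-week spleen), 0.004 (20-week spleen, down) and -0.114 (Foxp3, down). RLE factors gave -0.001 (2-week spleen, up), and a block gave -0.093 (thymus, up), 0.119 (2-week spleen, up) and -0.004 (20-week spleen, up). Calls with medians of 0.112 (10-week spleen, up), -0.027 (20-week spleen, down) and -0.258 (Tconv, down) were lost with an estimated correlation. Without single libraries, thymus ranged from -0.131 to -0.053 and -0.003 to 0.054, 2-week spleen from 0 to 0.144 (up) and -0.135 to 0.029 (down), 10-week spleen up from 0.055 to 0.156, 20-week spleen from 0.007 to 0.075 (up) and -0.076 to -0.002 (down), Tconv down from -0.297 to -0.122 and Foxp3 down from -0.136 to -0.004. A lone transduced library was assumed to vary like the other groups. Fits of the compared groups alone were not run for the cell type and reporter interactions, which already use those libraries. In the smallest library the floor of 3 counts was 6.68 CPM, which limits what low genes such as Pparg can show.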

Other observations

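No test in this part was chosen before its result was seen, and genes were named after their values were seen. Interferon-inducible GTPases were counted without a test of the group. Of 17 tested in VAT against splenic Treg, 1 fell in Tg- mice at 10 weeks (median log2 fold change -0.32), 12 in Tg+ mice at 10 weeks (-1.18), 12 in Tg- mice at 20 weeks (-1.05) and 13 in Tg+ mice at 20 weeks (-1.51). All 17 fell in Foxp3-transduced VAT cells (-2.17), and 9 rose with Foxp3 transduction in spleen (0.67). In VAT Tconv 1 of 16 rose and 0 fell (-0.12), while against Tconv 7 rose and 1 fell in splenic Treg (0.88), and 3 rose and 5 fell in VAT Treg (-0.21).

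The gamma chain constant segment Tcrg-C4 averaged 66.1 ± 16 CPM of the deposited counts in Tg+ splenic Treg at 10 weeks and 93.1 ± 18.3 at 20 weeks (SD, n = 3), against 4 and 2.34 in Tg- spleen and 0.99 and 1.58 in Tg+ VAT. At 2 weeks Tg+ spleen had 24.2. In reporter mice Tg+ PPARg- Treg had 107 and PPARg+ Treg 6.23, and Tconv had at most 0.894. In VAT Tconv Tcrg-C1 averaged 22 ± 19.9 and Tcrg-C2 9.32 ± 5.87 CPM, against 17.6 and 32.1 in those Treg at 10 weeks.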
